A study of Mus musculus with 12 samples.

How the data were processed

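Reduced representation bisulfite libraries were made from epithelial cells isolated from the colon of 6 C57BL/6 mice, 3 with induced Dnmt3b and 3 controls. Per the labels' protocols, genomic DNA was digested with MspI, a short (40 to 120 nt) and a long (120 to 220 nt) fragment band were taken from a gel, adapters with methylated cytosines were ligated, and the DNA was bisulfite-treated with additional conversion cycles, amplified by PCR and sequenced on a Genome Analyzer II. Induced mice drank water with 0.5 g/l doxycycline for 3 months, renewed every 3 days, and control mice regular water. The labels do not state whether control mice carried the transgene, and they give neither sex nor a sequencing date or batch. The 2 libraries of a mouse share its number in the labels, and the series design says that each mouse was split into 2 fractions.

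The deposited tables hold, per the file headers, the mean CpG methylation fraction per gene and per RefSeq promoter, from 0 to 1, with NCBI Gene ID, symbol and promoter accession, 1 table per library. The aligner, genome build, promoter window, coverage filter and conversion rate are not given in the sources used here. The authors' tables give no read counts or coverage, so the depth behind a fraction is unknown, no interval for counting error can be given, and a gene with few reads weighs as much as one with many. A level of 0% may rest on few reads. Breadth is given instead: 10358 to 10838 genes per short-fragment and 7278 to 8108 per long-fragment library, and 12098 genes and 13614 promoters over all libraries. Levels from bisulfite sequencing also read unconverted cytosine and hydroxymethylcytosine as methylation.

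Fractions were multiplied to percent, and differences are in percentage points. The gene value equalled the mean of the gene's listed promoters within 0.02 points in every library. Of the gene IDs 12076 (99.82%) were found in a RefSeq gene table of assembly GRCm38.p6, which was used only to match current symbols to list members, to order neighbouring genes and to find genes of the X and Y chromosomes. No 2 libraries of a fraction shared more than 1.54% (short) or 1.12% (long) of values above 0, so none was counted as a repeat. Genes with values identical to another gene in all 6 libraries, as bidirectional or overlapping promoters give, made up 16.67% of genes in the short and 19.13% in the long fraction. They were kept, so counts of changed genes include shared promoters.

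Genes present in all 6 libraries of a fraction were tested, 10027 in the short and 6127 in the long fraction. Induced and control mice were compared per fraction with limma 3.58.1 (lmFit and eBayes on percent levels) in R 4.3.3. Benjamini-Hochberg adjustment ran over the genes of a fraction, with a threshold of 0.05. Unless another fit, setting or omitted library is named, an adjusted p for a gene comes from this fit. Mean levels were compared with exact two-sided permutation tests, whose smallest p is 0.10 for 3 against 3 mice and 0.03125 for 6 pairs. The mice are separate animals. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 11 lists. Differences between fractions in the change were tested as an interaction in 1 limma fit over the 5309 genes in all 12 libraries, with mouse as a random block (consensus correlation 0.0674). Deviations of the short- and long-fragment libraries of a mouse from their group means had correlations across genes of 0.294, 0.613 and 0.290 for control mice 1, 2 and 3 and 0.198, 0.0559 and 0.394 for induced mice 1, 2 and 3. Not every library correlated best with its own mouse: the short-fragment library of control mouse 1 had 0.314 with the long-fragment library of control mouse 3, and that of induced mouse 2 had 0.0634 with that of induced mouse 1. Summary statistics and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

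The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the members of the methylation machinery list with Sfrp2, Sfrp4 and Sfrp5, the 10 largest rises and falls past the threshold without overlap between groups (filled to 5 with genes that did not pass), and up to 4 members per list with the largest absolute differences; some genes that the rule names are not reported here. The lists held 31 Wnt antagonists, 62 genes methylated in human colorectal cancer, 189 developmental transcription factors, 51 imprinted genes, 70 germline genes, 53 colon epithelium genes, 47 immune cell markers, 38 stromal, muscle and endothelial markers, 24 names for the methylation machinery and transgene sites, 40 housekeeping genes and 40 tumour suppressor or DNA repair genes; members were matched by symbol. They come from general knowledge and not from these libraries. A list of 99 X-linked names was written later, once the data were in hand, and before its own values were seen.

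The limma and list tests were tested on simulated levels, in which chosen genes were changed by known amounts. Levels were drawn independently for each gene, with its real control mean and the same pooled spread in both groups. Of 50 genes changed by 5, 10, 20 and 40 points, 68%, 68%, 78% and 92% were recovered in the short and 58%, 66%, 70% and 88% in the long fraction. In these data 13 of 166 calls in the short and 25 of 166 in the long fraction were false. A list raised by 20 points was called in both fractions, and 0 of 10 unchanged lists were. The simulated genes were uncorrelated, while the real lists had estimated correlations of up to 0.363 in the short and 0.823 in the long fraction. The simulation therefore cannot show how often camera calls an unchanged list of correlated genes. Alternatives covered genes present in at least 2 libraries per group, the mouse number as a block, a logit scale with an offset of 0.01, 1 fit over both fractions, trended and robust moderation, a minimum difference of 10 points, genes between 5 and 95%, centred libraries, omission of the X and Y chromosomes, other bins, and leaving out each library. Promoters as features, 1 gene per set of identical values, omission of the X-linked list, fry, cameraPR and bins from control mouse 1 were added after the data were seen. Coverage minimums and coverage-weighted means could not be computed without coverage.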

Results

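Promoter methylation was measured by reduced representation bisulfite sequencing, in which genomic DNA is cut with MspI, size-selected and bisulfite-treated so that CpG-rich sequence is enriched and unmethylated cytosines are read as thymine. The DNA came from epithelial cells isolated from the colon of C57BL/6 mice. In 3 mice the DNA methyltransferase Dnmt3b, which places methyl groups on previously unmethylated CpGs, was induced with doxycycline in the drinking water (0.5 g/l for 3 months), and 3 control mice drank regular water. Each mouse gave a short-fragment library (40 to 120 nt) and a long-fragment library (120 to 220 nt), 12 libraries in all. The values are mean CpG methylation levels per gene, averaged over its RefSeq promoters and given here in percent. The read depth behind a level is unknown. The short-fragment libraries listed 10358 to 10838 genes and the long-fragment libraries 7278 to 8108. The genome build and the promoter window are not given in the sources used here, so genes are named by symbol and NCBI Gene ID without coordinates. Doxycycline was given to the induced mice and not to the controls, so the drug and the induction were not separated.

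The comparison of induced with control mice asked how far raised Dnmt3b alters methylation at promoters of the colon epithelium. Mean promoter methylation was higher in the induced mice in both fractions. Over the 10027 genes present in all 6 short-fragment libraries it was 4.19% ± 0.331 (SD, n = 3) in control and 17.2% ± 1.10 (SD, n = 3) in induced mice, a difference of 13.01 percentage points. Over the 6127 genes present in all 6 long-fragment libraries it was 5.21% ± 0.379 (SD, n = 3) and 19.4% ± 1.60 (SD, n = 3), a difference of 14.2 points. All 3 induced mice lay above all 3 control mice in each fraction, and the exact two-sided permutation test gave p = 0.10 each time, the smallest value that 3 against 3 mice allow. Among all genes listed in a library, the share with a level above 50% was 3.19% ± 0.194 in control and 18.7% ± 1.56 in induced mice (SD, n = 3 each) in the short fraction, and 3.97% ± 0.331 and 20.3% ± 2.11 in the long fraction.

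**Figure D1:**
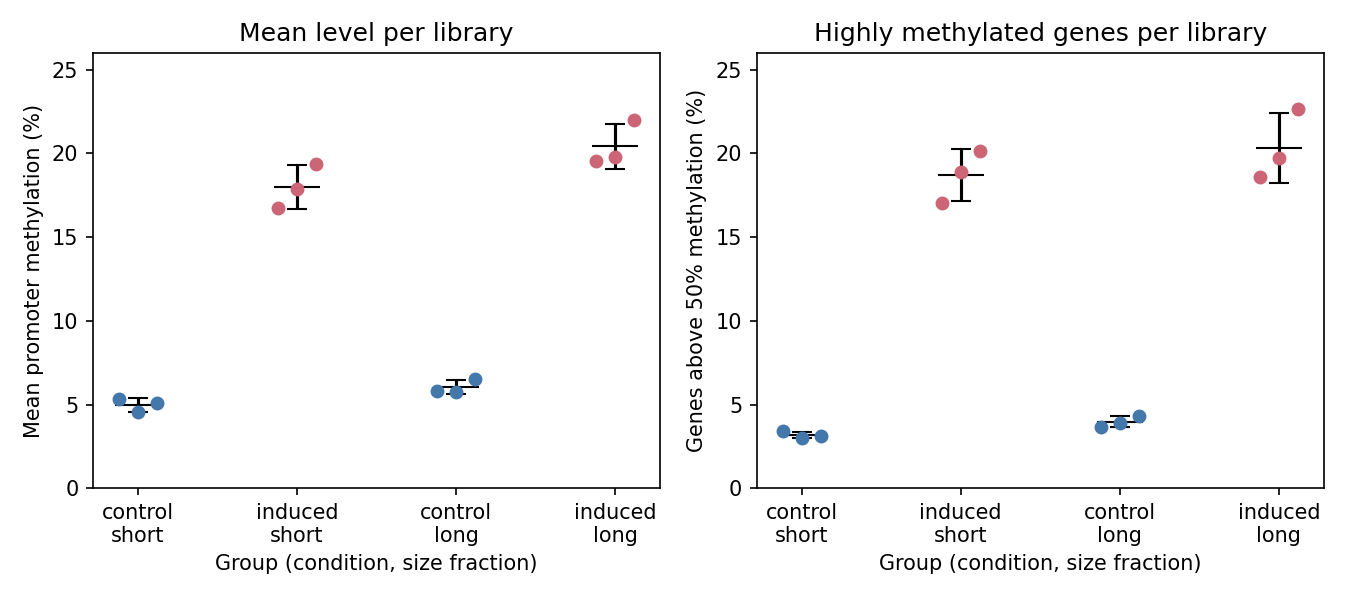
Mean promoter methylation (left) and the percentage of listed genes above 50% methylation (right) in each of the 12 libraries, by condition and size fraction; points are mice, horizontal marks and bars are the mean ± SD of 3 mice. The control means lie at 4.99% and 6.03% on the left, and the induced means at 18% and 20.4%.

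The increase fell on part of the genes. In the short fraction 2765 genes rose and 8 fell (limma, adjusted p under 0.05), and the median rise among those that rose was 49.0 points. In the long fraction 1421 genes rose and 1 fell, with a median rise of 54.6 points. A rise of more than 50 points was seen in 1347 genes of the short and 825 genes of the long fraction, while the median change over all genes was 0.50 and 0.943 points. Of the 9052 genes under 10% in control mice in the short fraction, 75.8% were still under 10% in induced mice and 14.1% had reached 50% or more; in the long fraction these shares were 72.0% and 14.8% of 5347 genes. All 3 induced values lay above all 3 control values for 39.5% of genes in the short and 38.2% in the long fraction, and below them for 0.908% and 0.277%, where chance gives 5% in each direction.

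The largest rises took promoters from nearly unmethylated to nearly full methylation. In the short fraction Fam132a (Gene ID 67389) went from 1.65% ± 2.85 to 94.9% ± 8.89 and Akap5 (238276), which encodes a kinase anchoring protein, from 0% in all 3 control mice to 91.0% ± 3.41. Esam (69524), an endothelial adhesion molecule, went from 3.96% ± 2.01 to 91.2% ± 8.60, and Mesp1 (17292), a transcription factor of early mesoderm, from 0.03% ± 0.0265 to 83.4% ± 14.1. Lbx2, Plcxd1, 4833427G06Rik, Cul9, 2410025L10Rik and Gpr153 complete the 10 largest rises, with induced means of 84.2% to 91.6%. In the long fraction Zfyve28 (231125) went from 1.21% ± 2.10 to 91.6% ± 4.27 and Nrxn2 (18190), a neurexin of synapses, from 1.49% ± 2.32 to 91.4% ± 4.61. Akap5 was among the 10 largest rises there too, from 2.39% ± 2.50 to 89.5% ± 6.43. Plekho1, Dync2h1, Fam131a, Otp, Tssk3 and 1700125D06Rik were among them as well, and the last 2 of these had identical values in every library. All SDs are over n = 3 mice, and the adjusted p of the genes in this paragraph ran from 6.83e-05 for Akap5 in the short fraction to 0.00577 for Dync2h1.

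Decreases were few and mostly small. In the short fraction Rasip1 (69903), a regulator of endothelial junctions, went from 10.8% ± 3.18 to 0.940% ± 0.830, Zfp768 (233890) from 11.5% ± 0.670 to 8.62% ± 0.646, Aes (14797), a Groucho-family corepressor, from 3.14% ± 0.898 to 0.237% ± 0.153, and Eif1a (13664), a translation initiation factor, from 2.04% ± 0.225 to 0.0333% ± 0.0493 (SD, n = 3 each). Zfp768 did not fall among long fragments, where it was at 3.38% ± 1.63 and 8.49% ± 2.71 (SD, n = 3; limma adjusted p = 0.128), and its change differed between the fractions in 1 fit over both (limma interaction, adjusted p = 0.0383). In that fit neither call of Zfp768 was as in the fit per fraction: the short-fraction change did not pass (adjusted p = 0.158) and the long-fraction rise did (adjusted p = 0.0141). Ndufs5, Stim1, Ppfia1 and M6pr fell from control means of 0.393% or less. In the long fraction Gmeb2 (229004) fell from 18.4% ± 4.74 to 4.59% ± 2.05 (limma adjusted p = 0.0307). Of these 9 genes only Eif1a and Ndufs5 stayed past the threshold whichever library was left out. Without control mouse 1 Rasip1, Aes and Zfp768 had adjusted p = 0.0730, 0.0575 and 0.0609. Without induced mouse 2 they had adjusted p = 0.0577, 0.05415 and 0.0544, and Gmeb2 had adjusted p = 0.103. Rasip1 also lost its call without induced mouse 3 and Zfp768 without induced mouse 1. Gmeb2 also lost its call without control mouse 2 or 3 or induced mouse 1 or 3. In the long fraction Rccd1 (45.1% and 37.98%), Id3 (11.4% and 5.02%), Jmjd5 (4.88% and 2.46%) and Nr1d2 (4.84% and 3.17%) had the largest mean decreases without overlap after Gmeb2 and did not pass.

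Leaving out control mouse 1, 2 or 3 lowered the count of changed genes from 1422 to 958, 910 or 904 in the long fraction. In data simulated with known changes 7.83% of short-fraction and 15.1% of long-fraction calls were false. The simulation gave 166 calls per fraction, against 2773 and 1422 in the real data. The share of false calls depends on how many genes truly change, so these shares need not hold for the real calls. A single fit over both fractions, on the 5309 genes in all 12 libraries, called 1575 genes in the short fraction, where the fit per fraction called 2773 of 10027 and, among those 5309, 1584 higher and 5 lower. Subtracting from each library its median difference from the mean library shifted the many genes near 0 and moved the split to 2844 higher and 2368 lower in the short and 1628 higher and 1938 lower in the long fraction.

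**Figure D2:**
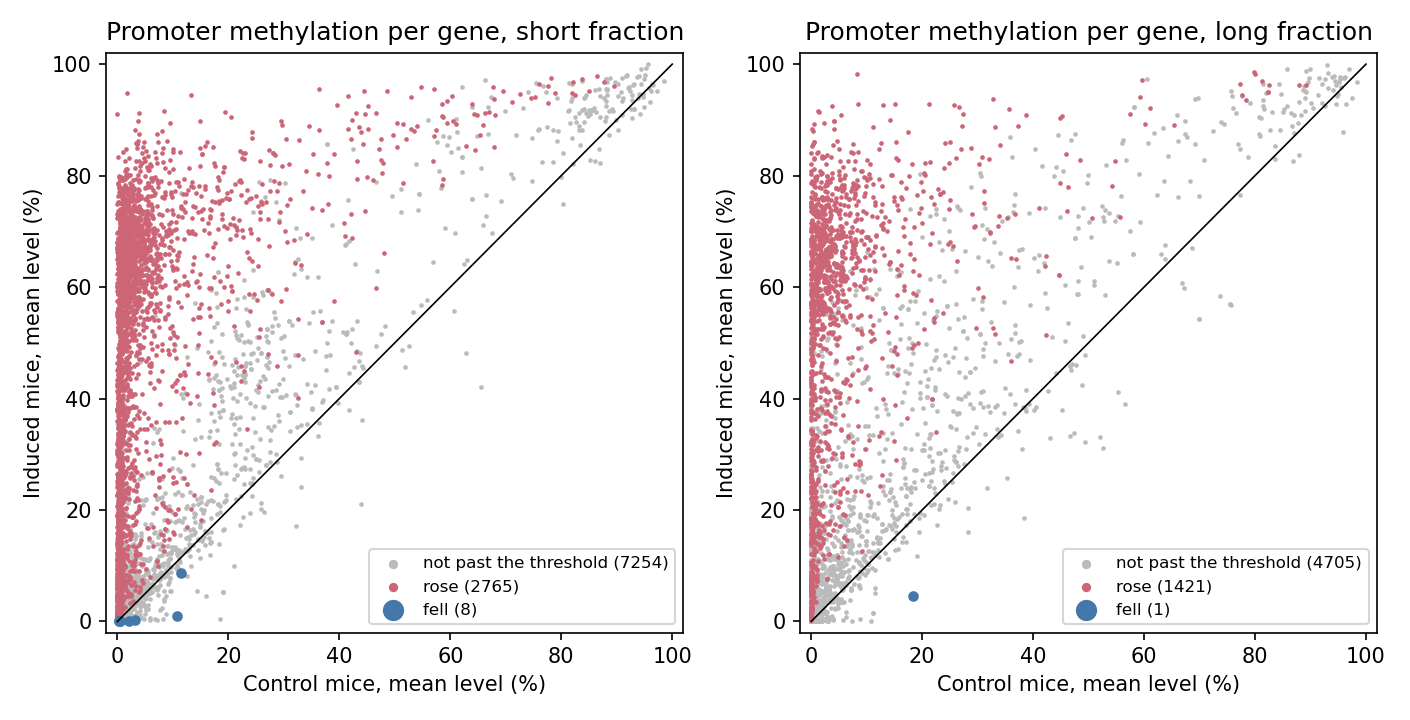
Mean promoter methylation of each gene in control mice (x axis, %) against induced mice (y axis, %), for the short fraction (left, 10027 genes) and the long fraction (right, 6127 genes); coloured points passed limma's adjusted p of 0.05 and the line marks equal levels. Genes that rose (2765 and 1421) lie above the line mostly from control levels under 10%, and 8 and 1 genes fell. Of all genes tested, 90.3% and 87.3% had control levels under 10%.

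The DNA methylation machinery, the list that holds Dnmt3b itself, stayed mostly low. At the Dnmt3b gene (13436) promoter methylation was 3.82% ± 0.166 in control and 5.35% ± 0.243 in induced mice in the short fraction (SD, n = 3 each, limma adjusted p = 0.00286). Among long fragments it was 0% in all 3 control mice and 2.03% ± 3.52 in induced mice, which did not pass (adjusted p = 0.584). These are methylation levels of the gene's promoter and say nothing of how much Dnmt3b the mice made. Dnmt1, the maintenance methyltransferase, was at 0.0267% and 0.583% (adjusted p = 0.0504) and Dnmt3a at 0.167% and 0.267% (adjusted p = 0.568). Of 14 members measured in the short fraction Dnmt3b alone rose, and of 10 in the long fraction Zfp57 alone, a zinc finger protein that protects imprints, from 0% in all 3 control mice to 55.5% ± 12.7 (SD, n = 3, limma adjusted p = 0.00726). Adjusted over the list alone, 1 member rose in each fraction. Uhrf1, which recruits Dnmt1, was at 7.97% and 22.4% in the short fraction (adjusted p = 0.0643) and at 0% and 0.0567% in the long fraction (adjusted p = 0.562). The X-linked gene Zbtb33 (22.1% ± 16.4 and 36.7% ± 3.45 in the short, 16.8% ± 11.2 and 41.2% ± 23.1 in the long fraction; SD, n = 3) varied widely between mice and did not pass. Among control mice it was lowest in mouse 2, at 3.47% and 5.19%, the mouse with X-chromosome levels near 0 described below. Induced mice varied in the long fraction as well, from 17.2% to 63.3%. Mbd4, a thymine glycosylase, was at 0% and 3.51% and Uhrf2 at 3.89% and 6.67%, neither past the threshold. Ezh2, Hells, Mbd1, Mbd2, Mbd3 and Tet2 in the short and Ezh2, Mbd1, Mbd3, Tdg, Trim28 and Uhrf2 in the long fraction had mean levels under 5% in both groups and did not pass.

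Wnt antagonists, which restrain the pathway that keeps intestinal stem cells dividing, rose as a group. In the short fraction 14 of 23 measured members rose and none fell, 15 when adjusted over the list alone, and the mean level went from 3.84% ± 0.448 to 35.8% ± 3.85 (SD, n = 3). Sfrp5 (54612) went from 7.10% ± 5.64 to 82.3% ± 11.4, Sfrp2 (20319) from 2.04% ± 1.73 to 71.0% ± 10.2 and Sfrp1 (20377) from 5.33% ± 1.996 to 71.5% ± 10.5 (limma adjusted p = 0.00173, 0.00122 and 0.00152); all 3 encode secreted proteins that bind Wnt. Nkd2, an inhibitor of Dishevelled, went from 0.393% to 72.1%. Among long fragments 9 of 14 members rose, 11 over the list alone, and the mean went from 3.82% ± 0.578 to 44.6% ± 10.1. Sox7 went from 2.54% ± 1.98 to 72.1% ± 8.32, the Wnt deacylase Notum from 0.423% to 56.1%, and Kremen2, a Dickkopf receptor, from 27.3% to 88.9%. Dkk3 was at 1.77% ± 1.58 and 66.8% ± 28.6 and did not pass (adjusted p = 0.0502). Sfrp2 and Sfrp5 were not present in all 6 long-fragment libraries and Sfrp4 not in all 6 of either fraction. Against all other genes the list stood higher with camera (adjusted p = 0.00691 and 0.00302), and not with an estimated correlation (adjusted p = 0.191 and 0.433).

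Genes known to be methylated in human colorectal cancer also rose as a group. Among short fragments 36 of 43 rose, 38 when adjusted over the list alone, and the mean level went from 3.28% ± 0.421 to 47.1% ± 5.65 (SD, n = 3). Bcat1 (12035), an enzyme of branched-chain amino acid breakdown, went from 3.05% ± 5.28 to 77.4% ± 6.53, the neurofilament gene Ina from 3.91% ± 3.33 to 75.8% ± 12.6, and the endothelin receptor gene Ednrb (13618) from 2.47% ± 1.60 to 72.0% ± 4.33. The metalloprotease inhibitor Timp3 went from 2.75% ± 2.38 to 73.7% ± 20.9, and its adjusted p was 0.0540 without control mouse 1 and 0.0505 without control mouse 3. Among long fragments 21 of 28 rose, 25 over the list alone, with means of 6.05% ± 1.27 and 51.8% ± 6.32. Ednrb again rose, from 3.60% to 75.7%, Neurog1, a neural transcription factor, from 0.147% to 70.1%, and Ndrg4 from 1.07% to 70.8%. Gata5 went from 4.27% ± 1.26 to 75.3% ± 22.99. It lost its call without control mouse 1, 2 or 3 or induced mouse 2 or 3. The adjusted p was then 0.0516 to 0.0852 and the change 62.9 to 71.7 points. The list stood above other genes with camera (adjusted p = 1.69e-09 and 1.40e-07) and not with an estimated correlation (adjusted p = 0.191 and 0.301).

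Homeobox and other developmental transcription factors, which pattern the body and its organs in the embryo, rose in nearly all cases. Among short fragments 158 of 173 rose, 164 when adjusted over the list alone, and the mean went from 4.57% ± 0.258 to 58.5% ± 5.50 (SD, n = 3). Nkx6-2 (14912) went from 1.32% ± 0.901 to 82.6% ± 3.40, Tbx5 (21388), a heart and forelimb factor, from 2.06% ± 1.93 to 83.1% ± 9.79, Foxe1 from 3.83% to 82.6% and Sox1, a factor of the early neural plate, from 0.523% to 79.2%. Among long fragments 112 of 135 rose, 122 over the list alone, with means of 4.15% ± 0.600 and 57.9% ± 7.24. Otp, Nr2e1, Sim2 and Lmx1b went from 0.277%, 1.94%, 2.02% and 3.64% to 88.1%, 83.5%, 83.2% and 83.4%. Foxa1 and Gata6, factors used by gut epithelium and chosen after their values were seen, did not pass in the short fraction. They were at 0.0567% and 0.24% in control and 0.0233% and 0.343% in induced mice. Gata5, a GATA factor of the colorectal cancer list, went the other way, from 4.27% to 75.3% in the long fraction. The camera test gave adjusted p = 1.45e-27 and 6.38e-22 for this list, against adjusted p = 0.191 and 0.301 with an estimated correlation.

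Imprinted and germline genes began from higher levels. Of 24 imprinted genes in the short fraction 10 rose (10 over the list alone), and the mean went from 23.05% ± 1.84 to 43.0% ± 2.17 (SD, n = 3); in the long fraction 3 of 25 rose (3 over the list alone), with means of 31.4% ± 1.52 and 47.6% ± 3.76. Rasgrf1 (19417) went from 1.67% to 79.8% in the short and from 2.24% to 73.1% in the long fraction, and Grb10 (14783), a growth factor receptor adaptor, from 1.66% to 70.8% and from 7.88% to 82.6%. Dlk1, a Notch ligand homologue, went from 0.287% to 62.4% and from 0.133% to 64.5%. Its long-fraction call was lost without control mouse 1, 2 or 3 (adjusted p = 0.0941, 0.0935 and 0.0938), with changes of 64.4, 64.4 and 64.3 points. Peg12 went from 30.5% to 74.8% in the short fraction and was at 21.4% and 61.5% in the long fraction without passing. Its short-fraction call was lost without control mouse 1 or 3 (adjusted p = 0.0557 and 0.0751) or induced mouse 1 or 3 (adjusted p = 0.0595 and 0.0636). Neither fraction set the imprinted list apart from other genes (camera adjusted p = 0.503 and 0.738). Of the germline genes, which are methylated in normal somatic tissue, 8 of 21 rose in the short (9 over the list alone) and 4 of 13 in the long fraction (4 over the list alone), from means of 65.7% ± 0.842 and 76.1% ± 2.43 to 80.4% ± 0.519 and 88.0% ± 1.59. Tdrd6 went from 17.96% to 78.0%, the pluripotency gene Pou5f1 (18999) from 58.4% to 92.9%, Gm1564 from 63.9% to 92.8%, and Syce2, a synaptonemal complex gene, from 0% to 30.7% in the short fraction. Among long fragments Smc1b, a meiotic cohesin gene, went from 59.3% to 94.1%, Dazl from 42.4% to 65.6%, Syce2 from 7.62% to 32.1% and Gm1564 from 65.3% to 89.0%, and each lost its call without at least 1 library (adjusted p = 0.0610, 0.0754, 0.106 and 0.111 without control mouse 2). The germline list as a whole was not set apart (camera adjusted p = 0.186 and 0.547).

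Genes of the colon epithelium itself mostly had low methylation in both groups. Among short fragments 4 of 22 rose, 4 over the list alone, and the mean went from 0.934% ± 0.569 to 6.41% ± 1.44 (SD, n = 3). The enteroendocrine gene Chga (12652) went from 1.65% ± 1.69 to 52.8% ± 14.1 and the crypt receptor gene Ephb3 from 0.12% ± 0.0608 to 4.25% ± 0.290. The tight junction gene Cldn4 went from 13.7% ± 8.54 to 64.2% ± 13.6 (adjusted p = 0.0538 without control mouse 1 and 0.0541 without control mouse 3). The stem cell factor Ascl2 was at 0.08% and 5.82% and did not pass. Among long fragments 2 of 22 rose, 2 over the list alone, with means of 2.67% ± 0.321 and 9.66% ± 0.199: Chga from 5.85% to 74.7% and Dclk1, a tuft cell gene, from 13.6% to 70.1% (adjusted p = 0.0505 without control mouse 3). Ephb3 (0% and 10.5%) and the secretory factor Atoh1 (0.337% and 7.76%) did not pass there. Cdx2 and Epcam, chosen after their values were seen, were at 0.173% and 0.123% and at 0% and 0.06% in the short fraction. The camera test did not set the list apart (adjusted p = 0.402 and 0.488).

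Many markers of cell types other than epithelium rose. Of the immune cell markers 3 of 5 rose in the short fraction (3 over the list alone), with means of 0.991% ± 0.275 and 38.7% ± 5.42, and 5 of 6 in the long fraction (6 over the list alone), with means of 12.5% ± 1.35 and 59.6% ± 4.90 (SD, n = 3). Ikzf1 (22778) and Ikzf3 (22780), lymphocyte transcription factors, went from 1.80% to 58.9% and from 0% to 66.8%, and the B cell factor Pax5 from 2.78% to 66.3% in the short fraction, where Runx1 was at 0% and 1.53% without passing. Among long fragments Gfi1 went from 0% to 80.3%, Ikzf1 from 0.82% to 62.4%, Ikzf3 from 2.59% to 59.9% and Coro1a from 12.6% to 73.6%. Of the stromal, muscle and endothelial markers 11 of 14 rose in the short (12 over the list alone) and 5 of 6 in the long fraction (6 over the list alone), from means of 10.98% ± 0.735 and 2.08% ± 0.767 to 55.7% ± 6.69 and 62.4% ± 15.3. The smooth muscle genes Myh11 (17880) and Cnn1 went from 9.75% to 76.1% and from 6.46% to 72.4%, and the endothelial receptor gene Kdr (16542) from 1.99% to 65.4%. Among long fragments the endothelial genes Sox18 and Flt1 went from 6.67% to 82.6% and from 1.11% to 73.6%. Col6a2 (1.12% ± 1.0 and 63.3% ± 27.8) in the short and Pdgfra (0% and 66.5%) and Des (3.54% ± 1.80 and 65.7% ± 25.6) in the long fraction rose as well. They lost their calls without control mouse 1 (adjusted p = 0.139, 0.0788 and 0.144), 2 or 3 or induced mouse 2, and Col6a2 and Des also without induced mouse 3. Camera gave adjusted p = 0.364 and 0.00132 for the immune and 0.00193 and 0.00508 for the stromal list. With an estimated correlation these were adjusted p = 0.439 and 0.301, and adjusted p = 0.191 and 0.433. Ikzf1 and Pax5 in the immune and Vim in the stromal list also belong to the colorectal cancer or transcription factor lists.

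Housekeeping genes and tumour suppressor or DNA repair genes had low mean levels in both groups, and few members rose. Of the housekeeping genes 1 of 31 rose in the short and 1 of 20 in the long fraction, and 0 in each when adjusted over the list alone by limma; their means were 2.68% ± 0.660 and 4.44% ± 0.243 in the short, 0.172% ± 0.215 and 2.50% ± 1.16 in the long fraction (SD, n = 3). The member that rose in the short fraction was Pgk1, a glycolytic gene on the X chromosome, from 5.70% to 29.2% (adjusted p = 0.0576 without control mouse 3). In the long fraction it was Eef2, a translation elongation factor, from 1.27% to 10.9%. Eef2 lost its call without control mouse 1 (adjusted p = 0.0711) or 2 or induced mouse 1 or 2. Hprt1, also X-linked, was at 19.2% ± 14.1 and 46.2% ± 0.732 in the short fraction and did not pass (adjusted p = 0.0699). There control mice 1, 2 and 3 were at 11.04%, 0% and 6.07% for Pgk1 and at 29.65%, 3.22% and 24.86% for Hprt1. Control mouse 2 was thus the lowest for both genes. Chmp2a (25.9% and 20.3%), Snrpd3 (14.03% and 19.3%), Ubb (0% and 27.4% ± 25.8) and Actb (0.31% and 3.14%) did not pass either. Camera placed the housekeeping list below other genes in the short fraction (adjusted p = 0.00193, and adjusted p = 0.191 with an estimated correlation) and gave adjusted p = 0.110 in the long fraction. Of the tumour suppressor and DNA repair genes 3 of 32 and 2 of 24 rose, 1 in each over the list alone, with means of 0.145% ± 0.0165 and 1.18% ± 0.0312 in the short and 0.164% ± 0.171 and 1.81% ± 0.201 in the long fraction. Rassf5 (54354), a Ras effector, went from 0.757% ± 0.584 to 22.1% ± 1.40 and from 0.510% ± 0.798 to 28.5% ± 4.92. Lats2 went from 0.887% to 3.25% and Trp53 from 0.02% to 5.41%. They lost their calls without control mouse 1 (adjusted p = 0.0740 and 0.147), 2 or 3 or induced mouse 2, and Trp53 also without induced mouse 3. Brca2 (0% and 2.04%) and Chek1 (0.98% and 2.56%) in the short and Rb1 (0.22% and 2.32%) and Cdkn1a (2.32% and 0.333%) in the long fraction did not pass. Camera gave adjusted p = 0.0580 and 0.223 for this list.

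No member of the 11 lists fell with limma. At an unadjusted p under 0.05, 0 of the 396 listed genes in the short and 0 of the 298 in the long fraction were lower. Over all tested genes 29 of 10027 and 2 of 6127 were lower at that p, and 8 and 1 fell. The lists are therefore not set apart by this. For the colon epithelium, machinery, housekeeping and tumour suppressor lists in both fractions and the imprinted list in the long fraction, the mean and median change were above 0 while camera's direction, which is relative to all other genes, was down. The machinery list had camera adjusted p = 0.443 and 0.306. Fry, which asks whether a list moves on balance without comparing it with other genes, called 10 lists in the short and 11 in the long fraction, the housekeeping list of the short fraction being the exception (adjusted p = 0.197).

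**Figure D3:**
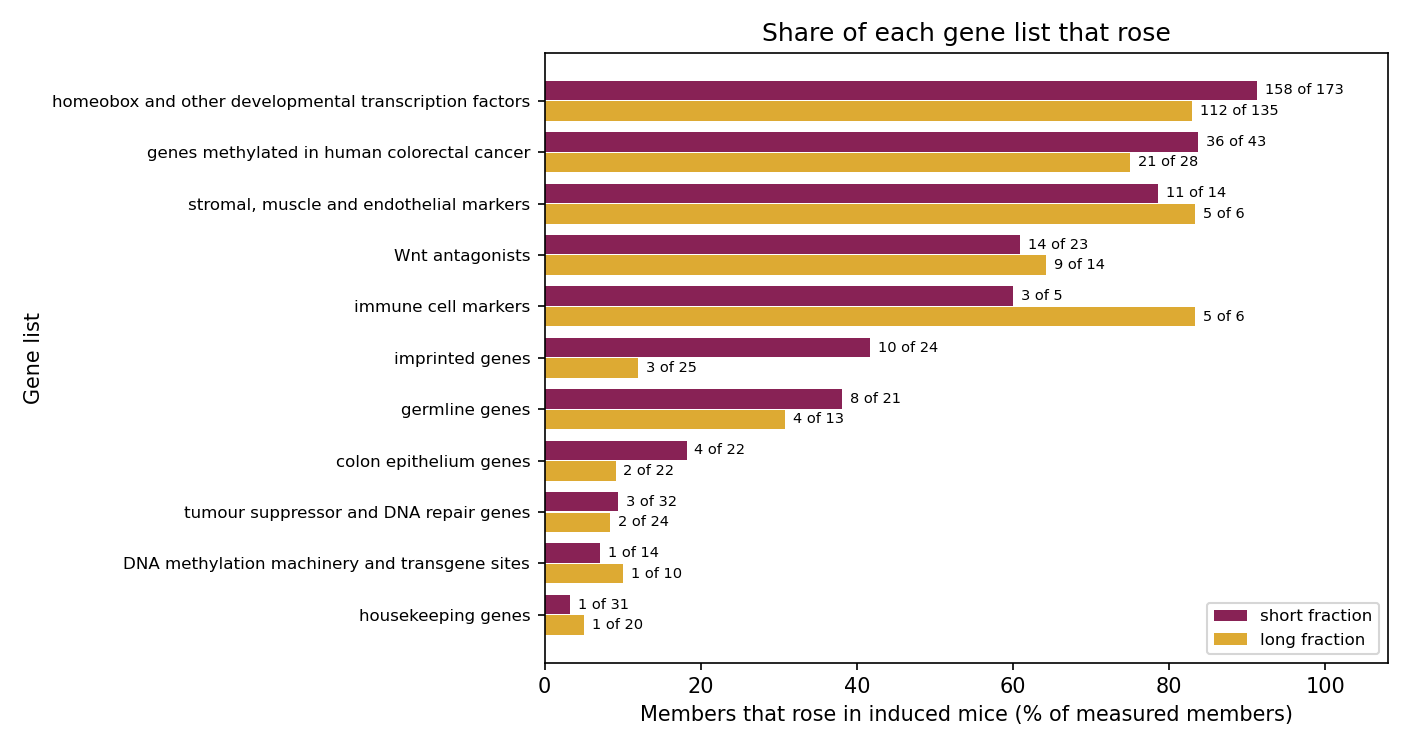
Percentage of measured members of each of the 11 gene lists that rose in induced mice (limma adjusted p under 0.05), with the counts beside the bars, for the short and the long fraction. The transcription factor list is highest in the short fraction (158 of 173), and the housekeeping list is lowest in both fractions (1 of 31 and 1 of 20).

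**Figure D4:**
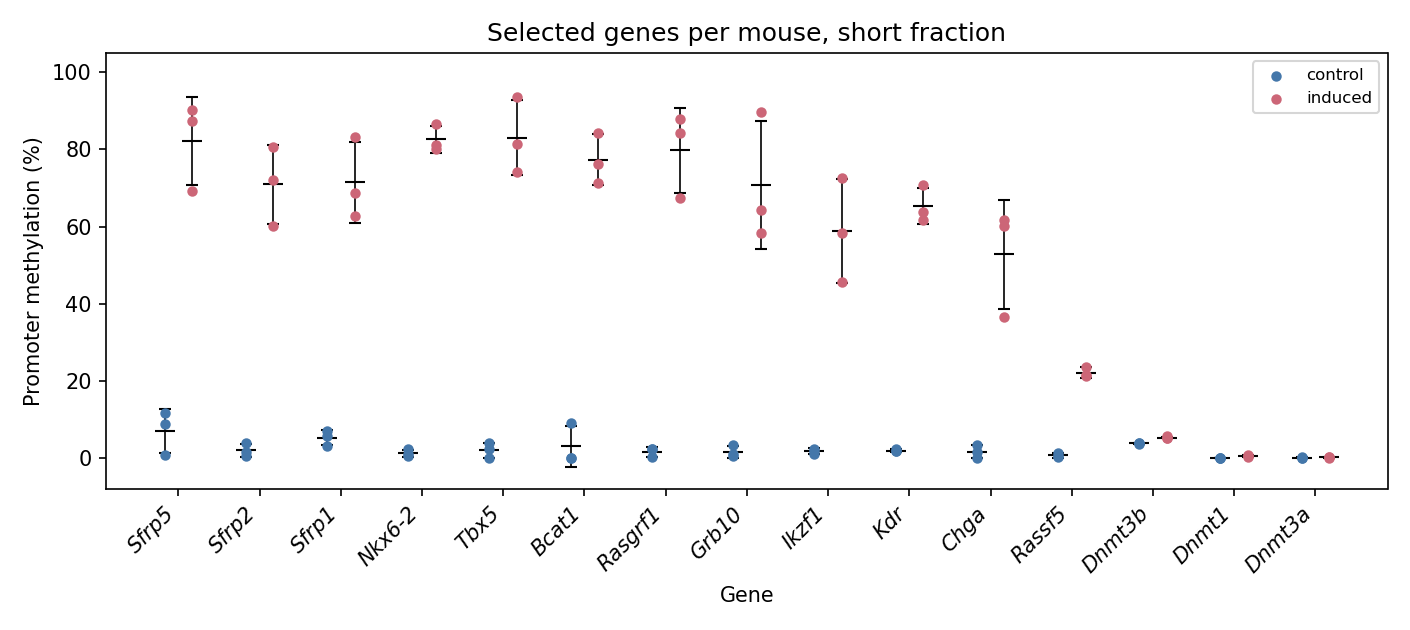
Promoter methylation (%) of 15 genes in the short fraction; points are the 3 mice of each group, horizontal marks and bars the mean ± SD. The control means of the genes from Sfrp5 to Rassf5 lie under 10% and the induced means range from 22.1% for Rassf5 to 83.1% for Tbx5, while Dnmt3b, Dnmt1 and Dnmt3a stay under 6% in both groups.

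Of the genes that rose, 2387 of 2765 in the short and 1205 of 1421 in the long fraction were under 10% in control mice. Among all genes tested, 90.3% and 87.3% were under 10% in control mice. At 10 to 50% in control mice, 323 of 748 and 195 of 617 genes rose. Under 10% it was 2387 of 9052 and 1205 of 5347. Genes were also grouped by their mean level over all 6 libraries, a measure that includes the change itself. Among short fragments the 7700 genes under 20% had a median change of 0.150 points (SD over the induced mice 0.0533), and all 3 induced values exceeded all 3 control values in 25.2% of them. The 2189 genes at 20 to 80% had a median change of 56.2 points (SD 6.53), with 89.5% higher without overlap, and the 138 genes at 80% or more a median change of 6.25 points (SD 0.445), with 40.6%. Among long fragments the medians were 0.140 points (SD 0.0301) over 4503 genes, 53.5 points (SD 8.79) over 1530 genes and 6.20 points (SD 0.903) over 94 genes, with 23.1%, 83.8% and 21.3% higher without overlap. A gene that rose from near 0 to near 100% has a middle mean and falls in the middle bin. With bins taken from the level in control mouse 1 and the change taken against control mice 2 and 3, a choice made after the data were seen, genes at 20 to 80% had median changes of 25.9 and 22.8 points and genes under 20% of 0.380 and 0.575 points.

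The short and long fractions cover different MspI fragments of the same mice, and their comparison asks whether the change of a gene was alike in both. Over the 5309 genes in all 12 libraries the induced minus control differences had a Pearson correlation of 0.935 and a Spearman correlation of 0.692, both across genes, which are not independent replicates. The covariance was 507, against 6.01 that the spread shared by the 2 libraries of a mouse adds with no effect, estimated from deviations within groups. The sign was the same in 75.6% of 4836 genes with a change other than 0 in both. Of these 5309 genes 1584 rose in the short and 1256 in the long fraction, and 1042 rose in both, where independent lists would share 375. In these genes 5 fell in the short fraction, 0 in the long and 0 in both. Akap5, Ednrb, Rasgrf1, Grb10, Dlk1, Chga, Ikzf1, Ikzf3 and Rassf5 were among the genes that rose in both fractions.

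Levels were slightly higher in the long than in the short fraction. Over the same 5309 genes the mean level of a mouse was 1.37 ± 0.396 points higher in its long-fragment library (SD, n = 6), in 6 of 6 mice (exact two-sided sign permutation test over mice, p = 0.03125, the smallest that 6 mice allow). The difference was 1.13 ± 0.0639 points in control and 1.62 ± 0.453 points in induced mice (SD, n = 3 each).

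Genes of the X chromosome were followed as a list because their promoter methylation depends on sex, which the labels do not give. In control mice 1, 2 and 3 the median level of the list was 37.5%, 0.00% and 32.5% over 49 genes in the short fraction and 35.7%, 0.00% and 42.2% over 31 genes in the long fraction. In induced mice 1, 2 and 3 it was 50.9%, 44.5% and 42.4%, and 54.9%, 48.6% and 52.5%. The median change of the list was 23.3 and 24.6 points with all mice and 11.95 and 13.1 points without control mouse 2, where 41 of 49 and 23 of 31 genes were higher in induced mice. Of the listed genes 2 and 0 passed limma's threshold, and without the list 2776 and 1423 genes changed, a setting added after the data were seen. A RefSeq gene table placed 229 and 136 measured genes on the X chromosome and 0 on the Y chromosome, and 55 and 14 of them rose. Their median levels in control mice 1, 2 and 3 were 33.96%, 0.11% and 33.2% in the short and 36.1%, 0% and 36.3% in the long fraction, and their median change was 25.1 and 27.8 points. Without control mouse 2 it was 14.8 and 16.9 points, with 204 of 229 and 107 of 136 genes higher. Without the X and Y chromosomes 2726 and 1413 genes changed.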

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

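The tests of incomplete conversion, of immune and stromal cells by their own markers and of sex on the whole X chromosome and outside the X-linked list, and the division of the sex test between the X-linked list and other genes, were chosen only after the results were seen. The change with induction differed between the short and long fractions in 250 of 5309 genes (limma interaction, adjusted p under 0.05), where the long minus short difference of the changes was above 0 in 140 and below 0 in 110. For Shroom3, an actin-binding regulator of epithelial shape, the change was -0.08 points in the short and 71.7 in the long fraction, a difference of 71.8. Gm88 had 6.91 and 67.8 points, a difference of 60.9, and Fam148c 22.99 and 76.6, a difference of 53.6. EG545963 (69.8 and 14.02 points) and Cpne9 (79.6 and 25.0 points) had smaller changes in the long fraction, with differences of -55.8 and -54.6. The long-fraction change of EG545963 did not pass in the limma fit over both fractions (adjusted p = 0.0510). Among the named genes Zfyve28 had changes of 66.9 and 90.4 points, a difference of 23.4, and Eef2 was at 0% in all 6 short-fragment libraries and 9.65 points higher with induction in the long fraction. Zfp768 had changes of -2.87 and 5.10 points, a difference of 7.98 with opposite signs, and Eif1a of -2.003 and 0.20 points, a difference of 2.20. The fractions hold different fragments of a promoter, and which CpGs they cover was not analysed here.

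Higher promoter methylation in the induced mice is the main pattern, and the design gives induced Dnmt3b as a hypothesis that these data cannot separate from doxycycline itself, since no mice received doxycycline without induction. Incomplete bisulfite conversion would raise all genes alike. Yet the housekeeping list had mean changes of 1.76 and 2.33 points in the short and long fractions, against 13.01 and 14.2 points over all genes. Its median changes were 0.00667 and 0.0533 points, against medians of 0.50 and 0.943 points over all genes. More immune cells or more stromal, muscle and endothelial cells would not raise markers whose promoters are unmethylated in those cells. Yet the median changes of these lists were 57.1 and 54.95 points in the short and 59.2 and 64.3 points in the long fraction. They rest on 5 and 6 of 47 immune and 14 and 6 of 38 stromal names in the short and long fractions. The unmethylated state was assumed and not measured, and each list pools several cell types. The values therefore argue only against more cells in which these markers are unmethylated. More of a single cell type, mixtures and other cell types stay open. Only 1 marker per fraction, Eng (5.98 points higher) and Cd37 (21.2 points higher), was over 50% in control mice and able to fall. A difference in sex fits the X-linked list: its median rise was 23.3 and 24.6 points, and control mouse 2 had a median of 0.00% in both fractions, consistent with a male among females, but without that mouse the list was still 11.95 and 13.1 points higher and all measured X-chromosome genes 14.8 and 16.9 points, so it alone does not account for all of the rise. Without that mouse 2318 and 910 genes changed in all, and of the 2718 and 1408 changed genes not on the X chromosome 2216 (81.5%) and 854 (60.65%) changed again, so a male control mouse does not account for most of them; the long-fraction count was also lower without control mouse 1 (958) or 3 (904), and the mean difference without mouse 2 was 13.995 points against 14.2, so the loss is not particular to that mouse.

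Only 1 of the 10 splits of the 6 mice, the real one, gave 2773 changed genes in the short or 1422 in the long fraction, and the highest of the other splits gave 2 and 1. For the lists past the threshold the real split gave 5 and 5 and the highest other 3 and 3, again with 1 split of 10 as large. With 10 splits the share cannot fall under 0.05.

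Levels differed between the 3 induced mice, for example 31.7%, 84.1% and 74.1% for Col6a2 in the short fraction. If this were error of single libraries, deviations of a mouse in its short and long libraries would be unrelated across genes; their mean correlation was 0.216, with 0.198 for mouse 1, 0.0559 for mouse 2 and 0.394 for mouse 3. The rule set beforehand asked each of the 3 mice to pass a minimum correlation, which mice 1 and 2 did not reach. Mouse 2 also did not correlate best with its own long library (0.0634 with that of mouse 1). Library error and a real difference between mice therefore cannot be told apart. No biological explanation was tested, as the labels give no difference between these mice.

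Changes of neighbouring genes were correlated at up to 20000 bases apart (0.107 in the short and 0.128 in the long fraction, against 0.0603 and 0.0915 as the highest of 1000 permuted gene orders). At larger distances the correlation was 0.0239 and 0.0096, within the permuted range, which is consistent with CpGs shared by adjacent promoters. Tandem gene families could not be weighed, because the distant pairs were already near 0: without pairs alike in their first 3 symbol letters they gave 0.0075 and -0.0034.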

How the results depend on the processing

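Settings with promoters, sets of identical values, the X-linked list, fry, cameraPR and bins from control mouse 1 were chosen after seeing the data. The mean level was higher in induced mice under every setting tried, with the smallest exact permutation p each allows (0.10, or 0.25 for 3 pairs). Without 1 library the differences were 12.4 to 13.5 (short) and 13.2 to 14.7 points (long). With the median over genes in place of the mean they were far smaller, 0.530 (short) and 0.953 points (long). The count of changed genes became 1575 in the short fraction in 1 fit over both fractions, which tested 5309 genes, and 5212 (short) and 3566 (long) with centred libraries, where genes near 0 in all libraries are shifted by construction. Without 1 library it was 2229 to 3061 (short) and 904 to 1560 (long), with 958, 910 and 904 in the long fraction without control mouse 1, 2 and 3. With the mouse number as a block it was 2114 (short) and 652 (long), and the block changed no list count. The count that fell, 8 (short) and 1 (long), was 15 and 1 on the logit scale and 4 and 2 for genes between 5 and 95%, and without 1 library 4 to 18 and 0 to 5. The numbers did not pair control with induced mice: same-number deviations had correlations of 0.0736, 0.00398 and -0.0499 (short) and 0.00102, 0.0366 and 0.0247 (long), and not every mouse correlated best with its own number.

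The lists past the threshold, 5 in each fraction, became 2 and 2 with genes present in at least 2 libraries per group, a setting that needs cameraPR, and 2 and 2 with cameraPR on the same genes, so the tool and not the gene set lowered the count. They became 0 and 0 with an estimated correlation (0 and 0 lists at an unadjusted p under 0.05), 10 and 11 with fry, and 5 to 6 (short) and 5 (long) without 1 library. Median changes with bins at 10 and 90% were 48.7 and 3.74 points for middle and high genes (short) and 0.0967, 42.8 and 2.99 for low, middle and high genes (long). With bins from control mouse 1 they were 0.380, 25.9 and 4.37 (short) and 0.575 and 22.8 for low and middle genes (long). Each setting puts other genes in a bin. With bins from control mouse 1 the change was also taken against control mice 2 and 3 only, and these 2 choices were not separated. Without 1 library the ranges were 0.117 to 0.160, 54.2 to 59.7 and 5.48 to 7.72 points (short) and 0.0950 to 0.147, 51.3 to 57.8 and 5.10 to 6.85 points (long). The correlation between fractions was 0.830 for genes at 5 to 95%, where the genes near 0 are absent, and 0.911 to 0.934 without 1 library. The difference between long and short fragments was 1.24 to 1.56 points with 5 mice, which cannot give a p under 0.0625.

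Genes that changed sign had not passed in either direction before. With centred libraries, which subtract the shared shift, Dnmt3a was at -0.296 and Tet2 at -0.232 points (short) and Ezh2 at -0.0917, Uhrf1 at -0.445 and Tdg at -0.455 (long), the last 2 past the threshold (limma adjusted p = 0.00593 and 0.00975). Without 1 library the ranges crossed 0 for Hells (-0.130 to 0.0700), Mbd1 (-0.407 to 0.208), Mbd3 (-0.0317 to 0.00833) and Chek1 (-0.705 to 2.87) in the short and Mbd3 (-2.85 to 0.0333) and Cdkn1a (-3.15 to 0.188) in the long fraction. The cause was not tested. The mean change of the germline list in the long fraction was 12.6 points with genes present in at least 2 libraries and 11.9 with cameraPR, where the test's direction turned to down, and that of the imprinted list was 14.01 to 17.4 without 1 library, turning to up at 16.96 points without control mouse 2. Of 52 named genes past the threshold in the short and 41 in the long fraction, 40 and 29 stayed past it whichever library was left out. Over all settings, 1598 values of named genes had the same call, 126 were no longer past the threshold and 42 newly past it. Unknown read depth limits every level, and 3 mice per group limit every test.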

Other observations

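Gene families named by their first 3 symbol letters differed in how often they rose, a grouping tested after the data were seen, with 1 gene per set of identical values and families of at least 20 genes (Fisher's exact test, adjusted over families). Fisher's test takes genes as independent units, but all calls of a fraction come from the same mice and genes can be correlated. Correlation within families was not estimated. The p-values of the families may therefore be too small, and they do not measure variation between mice. Potassium channel genes (Kcn) rose in 48 of 54 cases in the short fraction, 88.9% against 29.4% of other genes (adjusted p = 6.99e-18), and in 29 of 37 in the long fraction (adjusted p = 4.67e-10). The Cac family, mostly calcium channel genes, rose in 19 of 22 cases in the short fraction, fibroblast growth factor genes (Fgf) in 19 of 25, Hox genes in 28 of 36 and Gpr receptor genes in 25 of 38 (adjusted p = 9.53e-07, 3.07e-05, 8.93e-08 and 6.31e-05). Kcnk3 went from 1.43% to 76.0%, Cacna1b from 0.350% to 79.8% and Fgf20 from 2.62% to 75.4%, examples chosen after their values were seen. At the other end, proteasome genes (Psm) rose in 1 of 31 cases, ubiquitin-conjugating genes (Ube) in 1 of 30, zinc finger genes (Zfp) in 26 of 152 and mitochondrial complex I genes (Ndu) in 0 of 20 (adjusted p = 0.00298, 0.00298, 0.00298 and 0.00574). Among long fragments Hox genes rose in 11 of 21 cases and Ube genes in 0 of 21 (adjusted p = 0.0375 and 0.0193), Zfp genes in 15 of 91 without passing (adjusted p = 0.138), and the Cac, Fgf, Gpr, Psm and Ndu families had under 20 genes.

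The induced mice shared most of their large rises. With each induced mouse set against a different control mouse, 1895, 2016 and 1943 genes of the short fraction rose by at least 30 points in mice 1, 2 and 3, and 1664 of the 2244 genes seen in any mouse (74.2%) did so in all 3, where independent lists would share 73.8. In the long fraction the counts were 1165, 1279 and 1332, with 971 of 1553 (62.5%) in all 3, against 52.9.

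The changes of alternative promoters of a gene parted in a few cases. Of 958 genes with more than 1 listed promoter in the short fraction 110 had a promoter that was over 50 points higher in induced mice, and in 7 of these the changes of the promoters lay over 50 points apart. Among long fragments the counts were 609, 75 and 4. Each listed RefSeq accession counted as a promoter, and accessions of a gene with identical values were not merged. These counts therefore cannot show how often separate promoters change together. At Arhgef7 the promoter with the smallest change was at 0.0600% in induced mice and the one with the largest at 72.5%, and at Aldh7a1 they were at 1.26% and 69.5%. The changes parted for Dlgap4, Ece2 and Sept9 in both fractions, for Btbd11 and Rcan2 in the short and for Col18a1 in the long fraction. At Rcan2 and Col18a1 the promoter with the smaller change was already at 67.6% and 69.7% in control mice, and at 88.6% and 78.7% in induced mice. The other promoter rose from 0.503% to 73.0% and from 0.697% to 66.0%. The promoter levels of these genes were therefore closer in induced than in control mice.

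Igf2r, an imprinted gene chosen after its values were seen, had a lower mean in induced mice in both fractions, 62.8% and 48.2% in the short (limma adjusted p = 0.269) and 43.1% and 33.0% in the long fraction, and passed in neither.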
